A study of Mus musculus with 6 samples.

How the data were processed

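RPB1, the largest subunit of RNA polymerase II, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody to its N-terminal domain. The material was adrenal glands of 3 wild-type (WT) and 3 Armc5 knockout female mice of a mixed 129 sv and CD1 background, aged 10 to 14 months. Armc5 encodes an armadillo-repeat protein. The 6 libraries carry 6 different mouse numbers in the labels, so each was taken as a separate animal and n = 3 per genotype throughout. Groups and replicate numbers were taken from the sample titles and genotype labels.

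The deposited files held whole-number read counts per gene for 3 regions, the transcription start site (TSS), the gene body and the transcription end site (TES). Each region table had 12718 genes and 1 column per library, with no pooling of libraries. Another deposited count table had 38154 rows. It was planned as a table of peaks, but its rows were the 3 region tables stacked, with 0 cells that differed, and it is called the joint table. The authors also deposited log2 CPM (counts scaled to a common library total) of the joint table. Of these log2 values 0 differed by more than 1e-06 from values computed with the limma-voom formula from the joint counts and TMM-scaled library sizes, so they carried nothing beyond the counts and entered no test. Per the submitters' processing notes, the genome builds were GRCm38 and mm10, and the software included bcl2fastq 2.20, Trimmomatic, BWA, Picard, MACS2, HOMER, edgeR and limma, with no role or order given. The counting tool, the width of the TSS and TES windows, the read filters, the use of an input library and the choice of the 12718 genes are not given in the sources used here. The windows of neighbouring or overlapping genes can therefore share reads, as can near-identical gene copies such as histone genes, and single members of such families are uncertain. Gene symbols were matched to the NCBI RefSeq annotation of GRCm38.p6, and 12384 of the 12718 symbols matched. Coordinates are 1-based and from that annotation. Armc5 and Th were not analysed here.

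Each count table was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling within the table, the filterByExpr defaults (a minimum count of 10 and a minimum total of 15) and the quasi-likelihood F test of knockout against WT with no covariate. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size over the square root of F. The ratio of TSS or TES counts to gene body counts was tested per gene as a region by genotype interaction, with each library as its own block. Ratios of total counts were compared with an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1. CPM values are given as mean ± SD over the 3 mice of a genotype.

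A set of 27 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. The lists were steroidogenesis, cholesterol synthesis and uptake, zona glomerulosa, X-zone, chromaffin medulla, capsule and fibroblast, endothelium, macrophage and myeloid, lymphocyte, adipocyte, Schwann and glia, kidney tubule, Pol II subunits, RPB1 ubiquitylation and CUL3 adaptors, pausing and elongation factors, cell cycle, immediate early, p53 targets, NRF2 targets, heat shock and unfolded protein response, circadian clock, housekeeping, cAMP and PKA pathway, fatty acid and lipid droplet, ribosomal proteins, replication-dependent histones, and oxidative phosphorylation. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. An interferon-stimulated list was written after the data had been seen and is reported among the closing observations.

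The rule for named genes took, per table and direction, up to 8 called genes with the largest fold change among those whose 3 knockout libraries lay on the same side of all 3 WT libraries and whose mean CPM reached the median of tested rows. Symbols of predicted genes (Gm with digits, or ending in Rik) and of small RNAs were counted but not named. Where fewer than 5 genes were called in a direction, the 5 with the smallest p are given as values that did not pass. In the gene body 1 of these is not reported here. For the ratio tests up to 5 per direction were taken. Up to 3 called members of each list were added, with Polr2a, Star, Cyp11a1, Cyp11b1, Cyp21a1, Hsd3b1, Mc2r, Dbh and Chga as reference values. The genes beside Armc5 and the values of Cwc22 in all regions were added after their values had been seen.

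The alternatives were RLE scaling, table totals with no scaling factor, scaling by the joint table, no filter, a filter of 20 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma-voom with cyclic loess, the replicate number as a block, the form of the mouse number as a covariate, and leaving out each library in turn. For the ratios, gene body scaling for both regions and limma on the log2 ratio were also run. Chosen after seeing the data were a covariate for depth class (the 3 libraries with the fewest counts against the other 3), a covariate for the TSS to gene body ratio of a library, and totals without the predicted gene Gm10800.

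The procedures were tested on simulated counts drawn with the means, library sizes and spread of the real tables. At a 3-fold change 89.6% of simulated TSS genes, 94% of gene body genes and 91.8% of TES genes were recovered, against 36%, 60% and 38% at a 2-fold change. The joint table recovered 62% at 3-fold and 8% at 2-fold. The TSS and TES ratio tests recovered 68% and 54% at 3-fold, and 10% and 12% at 2-fold. False calls were 10 of 89 calls for the TSS ratio, 10 of 83 for the TES ratio and 7 of 82 in the joint table. They were 8 of 117 at the TSS, 7 of 137 in the gene body and 1 of 114 at the TES. Changes of 1.5-fold were recovered in at most 8% in any of these tests. With camera at the preset correlation, a list of 25 genes raised 1.5-fold was called, and 0 of 20 unchanged lists were. Genes were drawn independently, whereas the estimated correlation within real lists in the gene body reached 0.88 (ribosomal proteins). The simulation therefore does not show how often unchanged lists of correlated genes would be called. Nor did it hold a difference shared by many genes between libraries, such as that between the depth classes. The recovery and false call figures of single genes may therefore not carry over to the real tables. Figures were drawn with matplotlib 3.10.9.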

Results

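RNA polymerase II ChIP-seq with an antibody to the N-terminal domain of RPB1 was compared between adrenal glands of 3 WT and 3 Armc5 knockout mice. Each library gave counts over the TSS, gene body and TES of 12718 genes. The summed counts of the WT libraries were 22203948, 14511177 and 26748906 for replicates 1, 2 and 3, and those of the knockout libraries were 17936275, 28190157 and 24714835. TSS counts ranged from 1133364 to 3406223 per library, gene body counts from 12419812 to 22523647 and TES counts from 958001 to 2294430. The libraries differed in ways that genotype did not explain. WT replicates 1 and 2 and knockout replicate 1 had the fewest counts. In them the predicted gene Gm10800 took 10.9%, 25.1% and 11.7% of TSS counts, against 3.39%, 2.67% and 4.66% in WT replicate 3 and knockout replicates 2 and 3. The first principal component of log2 CPM separated these 3 libraries from the other 3 in each region and held 47.3% of the variance at the TSS, 60.9% in the gene body and 46.1% at the TES.

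**Figure D1:**
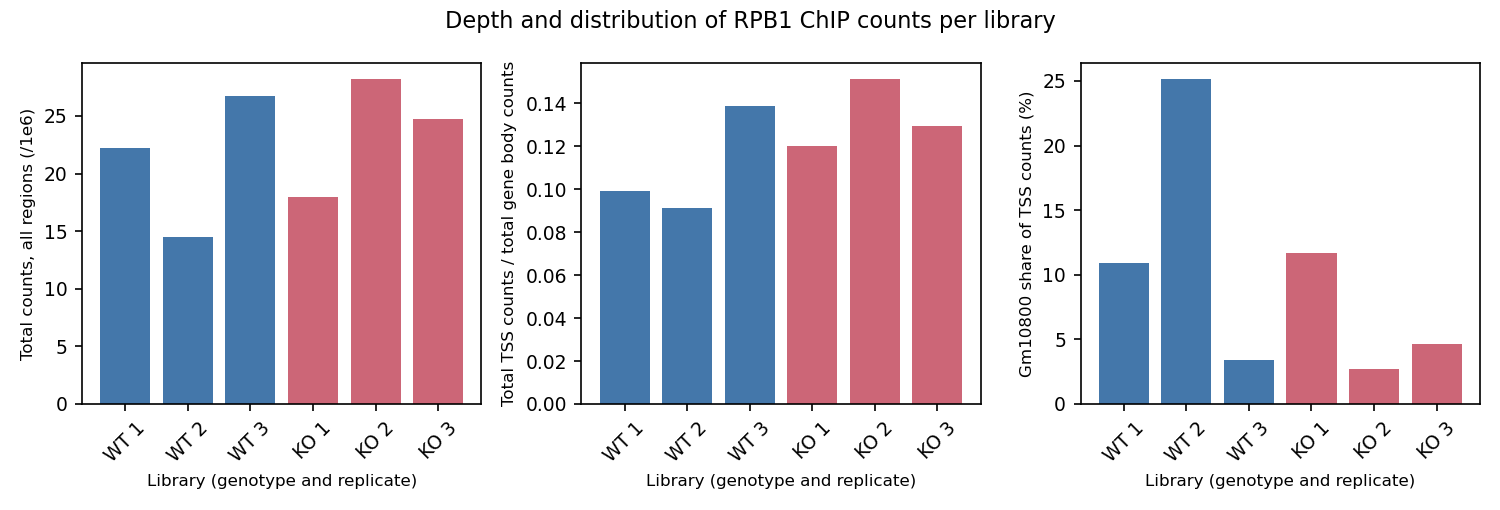
Bars show, for each of the 6 libraries, the total counts over all regions (divided by 1e+06), the ratio of total TSS to total gene body counts, and the percent of TSS counts in Gm10800, with WT in blue and knockout in red. WT replicates 1 and 2 and knockout replicate 1 had the fewest counts, and their Gm10800 share was 10.9% to 25.1%, against at most 4.66% in the other 3 libraries.

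The genotype was examined first at the targeted locus. Armc5 itself (GRCm38.p6, chromosome 7, 128237357 to 128245100) was not analysed here, so the rows of its neighbours were used, a choice made after their values were seen. The predicted gene 9130023H24Rik (chromosome 7, 128234451 to 128238031) overlaps Armc5 by 675 bp. Its TSS counts were 247, 242 and 618 CPM in the WT libraries and 16.9, 92.8 and 131 CPM in the knockout libraries. Its gene body counts were 17, 11.8 and 15.7 CPM in WT and 4.83, 5.23 and 4.24 CPM in the knockout. The gene body log2 fold change was -1.64 ± 0.21 (SE; edgeR quasi-likelihood test, adjusted p = 0.0368), and the TSS log2 fold change was -2.18 ± 0.54 (adjusted p = 0.243). In each of these tables its fold change ranked 2 from the lowest of all tested genes, after that of Cwc22. Its TES log2 fold change was -0.31 ± 0.28 (adjusted p = 0.959). Tgfb1i1, which encodes a focal adhesion adaptor and lies 1711 bp from the other end of Armc5, fell at the TES from 222 ± 81.3 to 92.6 ± 7.47 CPM (log2 fold change -1.26 ± 0.26, adjusted p = 0.00538). Its TSS and gene body log2 fold changes were -0.52 and -0.51 and did not pass (adjusted p = 0.918 and 0.934). The distance of 1711 bp is between the genes and was not measured from the TES. Slc5a2, 20582 bp away, had log2 fold changes of -0.03, 0.08 and -0.17 at the TSS, gene body and TES and did not pass. Of these 3 genes within 100 kb, 1 lay in the lowest 2.5% of fold changes in each table (two-sided Fisher's exact test, p = 0.0734, 0.0732 and 0.0731). It was 9130023H24Rik at the TSS and in the gene body, and Tgfb1i1 at the TES. The genes were chosen after their values were seen, so these p-values are not evidence for an effect at the locus. Reads of Armc5 cannot be separated from those of the gene that overlaps it. The gene body call of 9130023H24Rik ended with cyclic loess, joint table scaling and the mouse number covariate (adjusted p = 0.0541, 0.0902 and 0.09997). It also ended without WT replicate 1, WT replicate 3, knockout replicate 1, knockout replicate 2 and knockout replicate 3 (adjusted p = 0.2046, 0.0663, 0.139, 0.2094 and 0.2711), while its TSS fold change passed with depth class, enrichment and mouse number as covariates (adjusted p = 5.05e-08, 0.000413 and 0.00613), with joint table scaling (0.0196) and without knockout replicate 1 (0.0336).

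At the TSS, 43 of 12682 tested genes were called, and 43 were higher and 0 lower in the knockout. Mafa, a basic leucine zipper transcription factor known from pancreatic beta cells, rose from 23.5 ± 6.01 to 126 ± 5.30 CPM (5.23-fold; log2 fold change 2.39 ± 0.21, adjusted p = 0.00185). Rab11fip3, an effector of Rab11 in recycling endosomes, rose from 98.8 ± 10.2 to 371 ± 53.6 CPM (3.76-fold, adjusted p = 0.00185). Celf4, an RNA-binding protein of neurons, rose 4.55-fold, Rad51ap2 3.80-fold and Hap1, a huntingtin-binding protein, 3.45-fold. Mgat4a, a glycosyltransferase of N-glycan branching, rose 3.27-fold, Ddx60, an antiviral helicase, 3.20-fold and Hectd4, a HECT-domain protein, 3.15-fold. Unc50 lies 352 bp from Mgat4a, so their windows may share counts. The other called genes had log2 fold changes of 0.86 or more. The 5 genes with the smallest p among lower genes did not pass: Cwc22 (log2 fold change -2.96 ± 0.62, adjusted p = 0.109), Tm2d1 (-0.68), Col16a1 (-0.99), F3 (-0.96) and Rhbdf1 (-0.58), with adjusted p from 0.109 to 0.335.

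The TSS test was the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. All 43 called genes had groups that did not overlap, against 11.4% of tested genes and 10% by chance. In each region the call itself favours genes with separate groups, so such a share is not independent evidence for the calls. With depth class as a covariate 158 genes were called, 143 higher and 15 lower. Within each depth class 1 genotype had a single library, too few for a value within the class in any region. The count was 95 with DESeq2, 107 with joint table scaling and 75 with the mouse number covariate, and it was 14, 20, 84, 14 and 5 without WT replicate 1, WT replicate 2, knockout replicate 1, knockout replicate 2 and knockout replicate 3. The call of Celf4 ended with limma-voom and cyclic loess (adjusted p = 0.1076 and 0.0925) and without WT replicate 1, WT replicate 2, knockout replicate 2 and knockout replicate 3 (0.1407, 0.148, 0.1229 and 0.1467), and without knockout replicate 3 those of Rad51ap2, Hap1, Ddx60 and Hectd4 ended (0.0561, 0.0543, 0.0561 and 0.0561). Cwc22 passed as lower at the TSS with table totals, the mouse number covariate, joint table scaling, the enrichment covariate and depth class as a covariate (adjusted p = 0.0246, 0.00616, 0.00017, 0.00311 and 0.000577) and without WT replicate 2 and knockout replicate 1 (0.0355 and 0.00267). Tm2d1, Col16a1 and F3 passed as lower with depth class as a covariate (adjusted p = 0.0194, 0.00704 and 0.0217).

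Over gene bodies, 32 of 12714 tested genes were called, 31 higher and 1 lower in the knockout. Caprin2, an RNA-binding protein, rose from 50.7 ± 14.5 to 161 ± 12 CPM (3.18-fold; log2 fold change 1.67 ± 0.22, adjusted p = 0.0368). Baiap2, an adaptor of actin-rich protrusions, rose from 149 ± 31.4 to 413 ± 67.8 CPM (2.76-fold, adjusted p = 0.0444). Aatk lies 528 bp from Baiap2, so their windows may share counts. The phosphate transporter gene Slc20a1 rose 2.52-fold and the sulfate transporter gene Slc26a2 2.39-fold. Nabp1, a single-stranded DNA binding protein, rose 2.39-fold from 42.3 ± 4.15 to 101 ± 5.01 CPM. Kyat1, a kynurenine aminotransferase, rose 2.38-fold, Rcn2, a calcium-binding protein of the endoplasmic reticulum, 2.33-fold and Irf8, a transcription factor of myeloid cells and interferon responses, 2.19-fold. The 1 lower gene was 9130023H24Rik beside Armc5. Among lower genes that did not pass, Pdgfra, a receptor of fibroblasts, went from 150 ± 79.7 to 50.8 ± 5.21 CPM (log2 fold change -1.56 ± 0.38, adjusted p = 0.286). Adgrf5, F3 and Hk2 had log2 fold changes of -0.74, -0.80 and -0.82.

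The gene body test was the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and all 32 called genes had groups that did not overlap, against 10.4% of tested genes and 10% by chance. With depth class as a covariate 95 genes were called and with DESeq2 179. The count fell to 0 with the mouse number covariate, with joint table scaling, and without WT replicate 1, knockout replicate 1, knockout replicate 2 or knockout replicate 3, and to 12 without WT replicate 3. Pdgfra, Adgrf5 and F3 passed as lower with DESeq2 (adjusted p = 0.00397, 0.02 and 0.0237), and Adgrf5 with the enrichment covariate (0.034).

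At the TES, 116 of 12680 tested genes were called, 104 higher and 12 lower in the knockout. Hist1h1a, a linker histone gene, rose from 25.9 ± 13.4 to 161 ± 28.1 CPM (6.44-fold; log2 fold change 2.69 ± 0.29, adjusted p = 4.05e-08). Nabp1 rose from 34.0 ± 8.09 to 169 ± 11.5 CPM (5.02-fold, adjusted p = 4.05e-08). Serpinb1a, a protease inhibitor, rose 5.54-fold, Hspa1a, an inducible HSP70 chaperone, 4.39-fold and Ctsl, a lysosomal protease, 3.62-fold. Rtp4, an interferon-inducible gene, rose 3.42-fold and Kctd12, an auxiliary subunit of GABA-B receptors, 3.29-fold. Mc1r, a melanocortin receptor gene, rose 4.29-fold from 40.4 ± 7.76 to 171 ± 66.8 CPM. The neuronal tubulin gene Tubb3 lies 808 bp from Mc1r, Masp1 overlaps Rtp4 and Hspa1l lies 546 bp from Hspa1a, so these counts may be shared. Cwc22, a splicing factor gene (chromosome 2, 77881159 to 77946356), fell from 100.2 ± 84.2 to 6.06 ± 4.41 CPM (log2 fold change -4.21 ± 0.43, adjusted p = 2.86e-08). Pdgfra fell from 77.1 ± 44.9 to 23.2 ± 2.31 CPM (log2 fold change -1.71 ± 0.30, adjusted p = 0.000538), and Mgp, an inhibitor of matrix calcification, fell from 129 ± 57.0 to 42.7 ± 9.49 CPM (adjusted p = 0.00033). Heg1, a receptor of vascular endothelium, fell from 71.4 ± 17.9 to 37.7 ± 8.96 CPM (log2 fold change -0.90 ± 0.24, adjusted p = 0.049).

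The TES test was the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 116 called genes 110 had groups that did not overlap, against 11.5% of tested genes and 10% by chance. The count was 184 with depth class as a covariate, 69 with cyclic loess, 61 with joint table scaling and 73 without knockout replicate 2. The call of Cwc22 ended with limma-voom (log2 fold change -4.04, adjusted p = 0.0903) and cyclic loess (0.0975), and that of Mgp with cyclic loess (0.0605). Pdgfra had 26.6 CPM in WT replicate 1 and at most 24.6 CPM in the knockout, and its call ended with limma-voom, cyclic loess and the enrichment covariate (adjusted p = 0.0722, 0.239 and 0.0627). That of Heg1 ended with DESeq2, limma-voom, cyclic loess and the enrichment covariate (adjusted p = 0.18, 0.106, 0.165 and 0.114), with no filter and the stricter filter (0.0551 and 0.0567), and without WT replicate 2, WT replicate 3, knockout replicate 1 and knockout replicate 3 (0.21, 0.1061, 0.1385 and 0.2142).

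**Figure D2:**
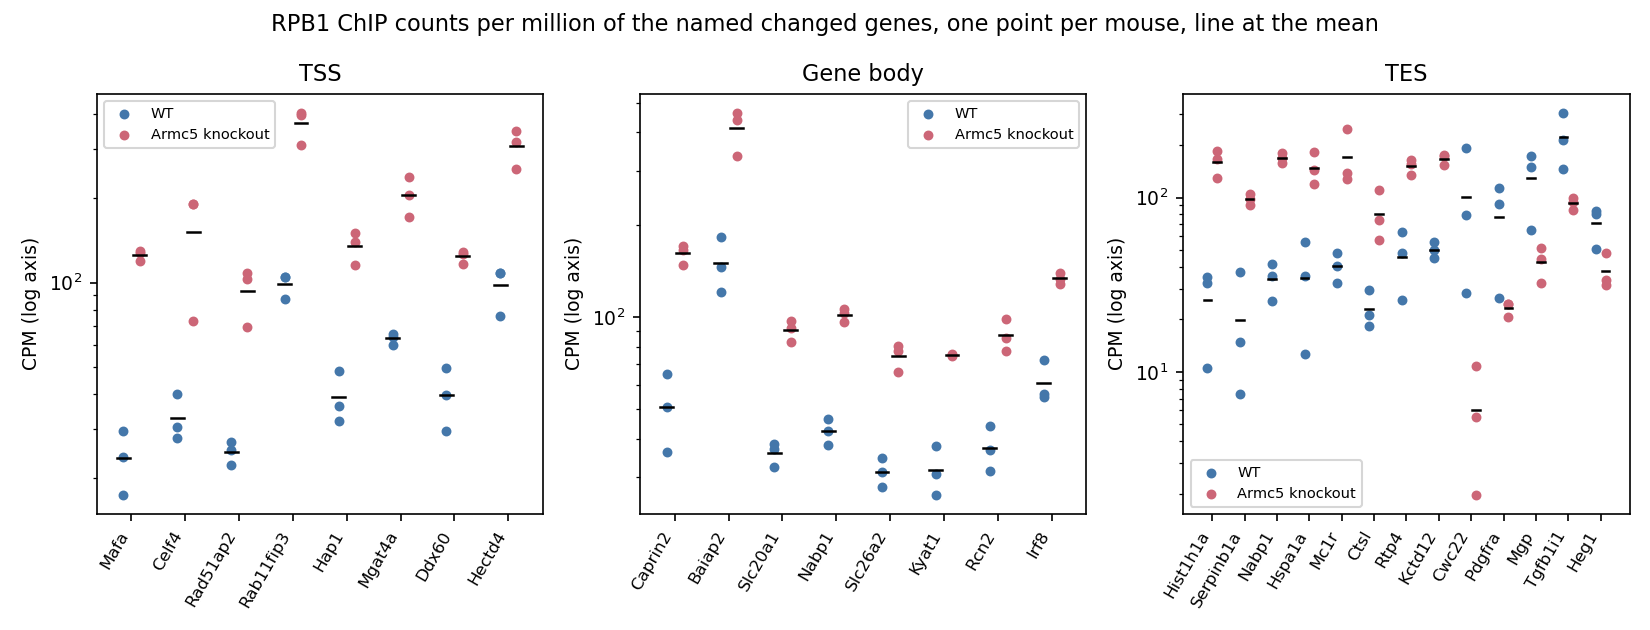
Points show CPM in each of the 6 mice on a log axis for the named called genes at the TSS, gene body and TES, with WT in blue, knockout in red and a line at the mean of 3 mice. The naming rule placed the 3 knockout mice above the 3 WT mice for each gene named as higher, such as Mafa (23.5 against 126 CPM). It placed them below for the 5 genes named as lower at the TES, so the separation shown is not added evidence.

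In the joint table, which tests the 3 regions on a common scale, 39 of 38073 rows were called, 38 higher and 1 lower, and 39 of 39 were also called in their own region's table. They were 22 TSS, 12 gene body and 5 TES rows. The TSS rows of Mafa (6.10-fold, adjusted p = 0.03), Rab11fip3 (4.48-fold), Hap1 (4.11-fold) and Mgat4a (3.92-fold), the gene body rows of Hist1h1a (4.90-fold) and Nicn1 (4.15-fold) and the TES rows of Nabp1 (4.67-fold) and Mc1r (3.96-fold) were the named rows that rose. The 1 lower row was the gene body of 9130023H24Rik. Lower rows that did not pass included the TES rows of Cwc22 (log2 fold change -4.29 ± 0.72, adjusted p = 0.0834), Mgp (-1.70), Tgfb1i1 (-1.36) and Rgmb (-1.14) and the gene body row of Adgrf5 (-0.82). The joint count was 62 with table totals only, 289 with DESeq2, 13 with the mouse number covariate and 241 with depth class as a covariate. It was 0, 78, 23, 0 and 0 without WT replicate 1, WT replicate 3, knockout replicate 1, knockout replicate 2 and knockout replicate 3. The call of the Mc1r row ended with RLE scaling, the stricter filter, limma-voom, cyclic loess and the mouse number covariate (adjusted p = 0.0571, 0.0503, 0.0526, 0.0545 and 0.0542) and without WT replicate 2 (0.0615). With the mouse number covariate those of Hist1h1a, Nicn1, Mgat4a and Hap1 ended (adjusted p = 0.0542, 0.0542, 0.0542 and 0.0562), as did those of Hist1h1a without WT replicate 2 (0.0586) and of Hist1h1a and Nicn1 without knockout replicate 1 (0.0511 and 0.0566). The lower rows of Cwc22, Mgp and Tgfb1i1 passed with depth class as a covariate (adjusted p = 0.00232, 0.0223 and 0.0046) and with DESeq2 and the enrichment covariate, that of Adgrf5 with DESeq2 and the enrichment covariate (0.0142 and 0.029), that of Rgmb with DESeq2 (0.024), and that of Cwc22 without WT replicate 2 and WT replicate 3 (0.0323 and 0.0447).

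Genes called in more than 1 region were higher in the knockout, and 22 of the 31 higher gene body calls were also called at the TES. Lower calls numbered 0 at the TSS, 1 in the gene body and 12 at the TES, so lower genes could hardly be shared. Ahcy, the enzyme that removes S-adenosylhomocysteine, Hist1h1a and Pcdh8, a protocadherin gene, were called at the TSS, gene body and TES, and were named because they were the 3 genes shared by all regions. TSS and gene body shared 6 higher genes, among them Fabp5 and Rcn2, where independent lists would share 0.105. TSS and TES shared 12, among them Ddx60, Ifit1, Ifit3, Oas1a and Rsad2, against 0.354, and gene body and TES shared 22, among them Nabp1, Irf8, Oasl2, Slc20a1 and Slc26a2, against 0.254. These members of the shared sets were chosen after their values were seen. The regions were counted in the same libraries, so the overlaps are not independent evidence. Window widths are not known, so the regions of a short gene may also share reads. Across 12643 genes, which are not independent replicates, Spearman's correlation of fold changes was 0.16 between TSS and gene body, 0.15 between TSS and TES and 0.43 between gene body and TES.

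Whether the distribution of RPB1 along genes differed by genotype was examined with ratios. The ratio of TSS to gene body counts was called for 0 of 12679 genes with edgeR, with 462 at an unadjusted p under 0.05, and for 0 with limma on the log2 ratio, with 533. The smallest p-values among higher ratios belonged to Pced1b (2.77-fold), Mgat4a (3.60-fold), Rab11fip3 (3.62-fold), Hectd4 (3.60-fold) and Ctdsp2 (2.43-fold), and those among lower ratios to Kctd12 (log2 change -1.41 ± 0.21), Amigo2 (-1.21), Nicn1 (-1.66), Nabp1 (-1.17) and Hapln3 (-1.78), with adjusted p from 0.141 to 0.51. The ratio of TES to gene body counts was called for 2 of 12677 genes, both with adjusted p = 0.0495. That of Mc1r rose 4.06-fold (log2 change 2.02 ± 0.30), and that of 2810006K23Rik fell (log2 change -1.24 ± 0.19), the latter named because the count was 2. Rtp4 (2.41-fold, adjusted p = 0.097), Shf, Usp5 and Nabp1 were next among higher ratios, and Edn2 (log2 change -2.42), Gstp2 (-1.90), Mt2 (-1.11), Wdr11 (-1.15) and Rgmb (-0.99) had the smallest p among lower ratios and did not pass. With depth class as a covariate 27 TSS ratios (9 higher and 18 lower) and 9 TES ratios were called, among them the 10 TSS ratios named above and the TES ratios of Rtp4, Shf, Usp5, Nabp1, Edn2 and Gstp2. The TES ratio count was 0 with RLE scaling, gene body scaling, limma, and without WT replicate 1, knockout replicate 2 or knockout replicate 3, and 15 without WT replicate 3. Without WT replicate 2 the call of the Mc1r ratio ended (adjusted p = 0.0846). The TES ratios of Rtp4, Shf, Edn2, Gstp2 and Mt2 passed without WT replicate 3 (adjusted p = 0.0447, 0.0195, 0.0174, 0.039 and 0.039), and that of Gstp2 without knockout replicate 1 (0.0235).

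Summed over all genes, the TSS to gene body ratio was 0.110 ± 0.0255 in WT and 0.134 ± 0.0160 in knockout libraries (SD, n = 3 each; exact two-sided permutation test, p = 0.3). The TES to gene body ratio was 0.0917 ± 0.0149 in WT and 0.0972 ± 0.00771 in the knockout (exact p = 0.7). The smallest p this design allows is 0.1. In the 3 libraries with the fewest counts the TSS ratio was 0.0992 and 0.0912 in WT and 0.120 in the knockout, and in the other 3 it was 0.139 in WT and 0.151 and 0.129 in the knockout. Scaling within a table centres its fold changes, so a general shift cannot be read from them. With joint table scaling in place of scaling within the table, the median log2 fold change of all genes moved from -0.01 to 0.24 at the TSS, from -0.02 to -0.12 in the gene body and from -0.02 to -0.12 at the TES. Changes are reported relative to each table's own scale.

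Among the gene lists, replication-dependent histones were higher in the knockout in all 3 regions. In the gene body their median log2 fold change was 0.68 over 34 genes (camera, adjusted p = 2.36e-19; adjusted p = 0.529 with an estimated correlation). At the TSS it was 0.22 (adjusted p = 5.57e-07; 0.875 as the adjusted p with an estimated correlation) and at the TES 0.36 (adjusted p = 4.85e-06; 0.519 as the adjusted p with an estimated correlation). Of the members, 2 rose at the TSS, 1 in the gene body and 6 at the TES, and 0 fell. Adjusted over the list alone the counts were 11, 12 and 6. Hist1h1a rose 5.34-fold in the gene body, Hist1h2bm 2.70-fold at the TSS and Hist1h4i 2.63-fold at the TES. The call of Hist1h2bm ended without WT replicate 1, WT replicate 2, knockout replicate 2 and knockout replicate 3 (adjusted p = 0.1293, 0.0889, 0.1229 and 0.1467). Near-identical histone copies can share reads, so single members are uncertain. The heat shock and unfolded protein response list was higher in the gene body (median 0.35, adjusted p = 2.6e-08) and at the TES (median 0.27, adjusted p = 2.3e-05), with adjusted p = 0.529 and 0.519 with an estimated correlation. At the TES 3 of its 28 members rose, or 5 adjusted over the list alone, namely Hspa1a, Hspa1b (2.42-fold) and Dnajb9, an endoplasmic reticulum chaperone (1.89-fold). Hspa1a and Hspa1b are near-identical copies. The call of Hspa1b ended with cyclic loess (adjusted p = 0.0516). That of Dnajb9 ended with cyclic loess and joint table scaling (adjusted p = 0.0678 and 0.1159) and without WT replicate 1, WT replicate 2, WT replicate 3, knockout replicate 1 and knockout replicate 2 (0.072, 0.0639, 0.0934, 0.097 and 0.1684). The immediate early list, genes such as Fos and Egr1, was higher at the TSS (median 0.23, adjusted p = 0.0297), gene body (0.35, adjusted p = 4.96e-07) and TES (0.23, adjusted p = 0.00324), with adjusted p = 0.875, 0.529 and 0.519 with an estimated correlation, and 0 members passed singly.

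Lists of cell types of the gland and of steroid synthesis also moved. The capsule and fibroblast list was lower at the TSS (median -0.70, adjusted p = 0.0127), gene body (-0.46, adjusted p = 2.76e-06) and TES (-0.69, adjusted p = 6.74e-06), with adjusted p = 0.875, 0.578 and 0.519 with an estimated correlation. Of its 11 members 3 fell at the TES, or 4 adjusted over the list alone, and these were Pdgfra, Mgp and the collagen gene Col3a1 (log2 fold change -1.33 ± 0.31, adjusted p = 0.0145). The call of Col3a1 ended with DESeq2, cyclic loess and the enrichment covariate (adjusted p = 0.0523, 0.0649 and 0.1497) and without WT replicate 2, knockout replicate 2 and knockout replicate 3 (0.1325, 0.0937 and 0.0547). The chromaffin medulla list, which marks the catecholamine-producing cells, was higher at the TSS (median 0.28, adjusted p = 0.0467), gene body (0.79, adjusted p = 8.36e-05) and TES (0.52, adjusted p = 0.000207), with adjusted p = 0.875, 0.655 and 0.519 with an estimated correlation. In linear fits to log2 CPM its medians were 0.23, 0.65 and 0.44 without a covariate and 0.24, 0.34 and 0.20 with depth class as a covariate. None of its 19 members passed over all genes, and 0, 1 and 2 did adjusted over the list alone. Chga, a granin of chromaffin granules, had 90.1, 67.8 and 181 CPM in the gene body in WT and 88.3, 346 and 175 CPM in the knockout (adjusted p = 0.934). The steroidogenesis list was higher in the gene body (median 0.24, adjusted p = 0.00746) and at the TES (0.26, adjusted p = 0.0121), with adjusted p = 0.655 and 0.519 with an estimated correlation and 0 of 21 members past the threshold. The endothelium list was lower at the TES (median -0.18, adjusted p = 0.0121; adjusted p = 0.519 with an estimated correlation). Lists of general function moved as well. The housekeeping list was higher in the gene body (median 0.21, adjusted p = 0.000293) and at the TES (0.23, adjusted p = 0.0121), ribosomal proteins in the gene body (0.23, adjusted p = 4.59e-09) and oxidative phosphorylation in the gene body (0.08, adjusted p = 0.0474), with adjusted p = 0.655, 0.519, 0.655 and 0.819 with an estimated correlation. In the fits to log2 CPM the gene body medians of ribosomal proteins and oxidative phosphorylation went from 0.28 and 0.09 to 0.10 and -0.00415 with depth class as a covariate, and the TSS median of the immediate early list from 0.24 to 0.12.

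With the preset correlation 4 lists were called at the TSS, 9 in the gene body and 8 at the TES of 22 tested in each, and 0 held with an estimated correlation or with fry. With depth class as a covariate the calls of chromaffin medulla and immediate early at the TSS, oxidative phosphorylation in the gene body and housekeeping at the TES ended (adjusted p = 0.134, 0.0745, 0.818 and 0.0901). Without WT replicate 2 the calls of chromaffin medulla, capsule and fibroblast, and immediate early at the TSS ended (adjusted p = 0.0894, 0.2514 and 0.1707). So did those of steroidogenesis, housekeeping, ribosomal proteins and oxidative phosphorylation in the gene body (adjusted p = 0.846, 0.2, 0.538 and 0.2968) and of steroidogenesis, immediate early and housekeeping at the TES (0.3785, 0.2033 and 0.5491). In the fits to log2 CPM these gene body medians went from 0.258, 0.242, 0.275 and 0.0896 to 0.103, 0.0327, 0.0241 and -0.0228 without this library. The TES medians went from 0.298, 0.292 and 0.257 to 0.181, 0.146 and 0.0814. Without WT replicate 3 the calls of chromaffin medulla, capsule and fibroblast, and immediate early at the TSS (adjusted p = 0.3436, 0.1479 and 0.0609), steroidogenesis in the gene body and TES (0.0867 and 0.3298) and endothelium at the TES (0.1199) ended. Without knockout replicate 2 those of chromaffin medulla at the TSS and TES (adjusted p = 0.771 and 0.121), capsule and fibroblast at the TSS (0.0528) and steroidogenesis and oxidative phosphorylation in the gene body (0.0514 and 0.1725) ended. The chromaffin medulla medians in the fits to log2 CPM then went from 0.234 to 0.114 at the TSS and from 0.441 to 0.129 at the TES. The calls of oxidative phosphorylation in the gene body and endothelium at the TES ended without WT replicate 1 (adjusted p = 0.1164 and 0.1797), that of steroidogenesis at the TES without knockout replicate 1 (0.1652), and those of immediate early at the TSS and oxidative phosphorylation in the gene body without knockout replicate 3 (0.1295 and 0.207). Ribosomal proteins at the TES were called as lower without WT replicate 2 (adjusted p = 0.0122) and as higher without WT replicate 3 (1.63e-05). Oxidative phosphorylation was called as lower at the TES with depth class as a covariate and without WT replicate 2 (adjusted p = 0.0256 and 0.0122), and at the TSS without WT replicate 2 and knockout replicate 1 (0.0308 and 0.044). At the TSS steroidogenesis and the heat shock list were called as higher with depth class as a covariate (adjusted p = 0.0296 and 0.015), without WT replicate 1 (0.0243 and 0.0243) and without knockout replicate 3 (0.0329 and 0.0199), and endothelium in the gene body as lower without WT replicate 2 (0.0407).

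**Figure D3:**
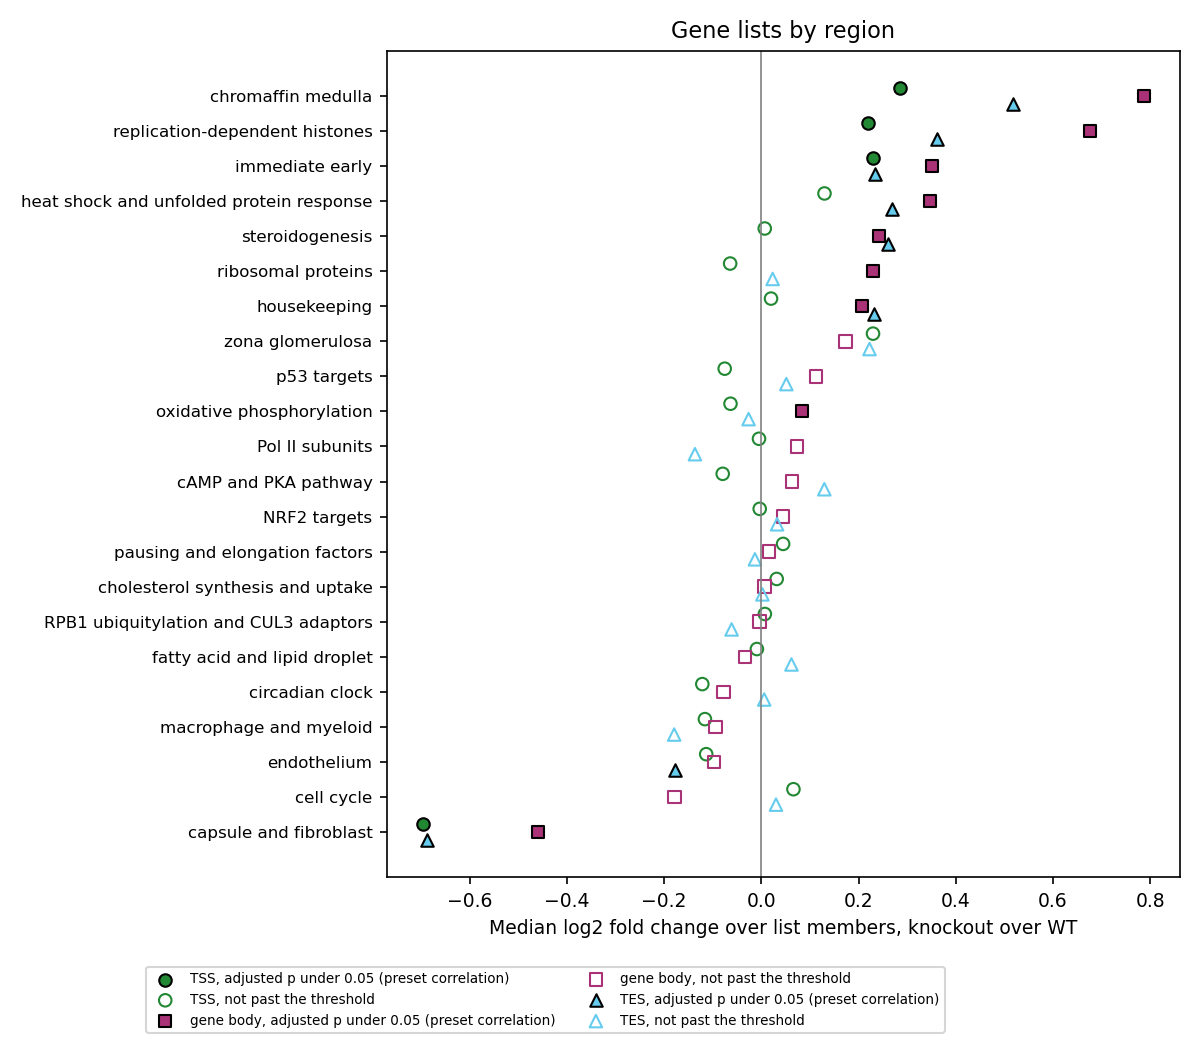
Points show the median log2 fold change of knockout over WT over the members of each tested list at the TSS (circles), gene body (squares) and TES (triangles), filled where camera with the preset correlation gave an adjusted p under 0.05. Chromaffin medulla and histones lay highest in the gene body (0.79 and 0.68), and capsule and fibroblast lay lowest in all 3 regions (-0.70, -0.46 and -0.69). In linear fits to log2 CPM these 2 gene body medians were 0.65 and 0.70, and with depth class as a covariate they were 0.34 and 0.76.

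The other 12 tested lists were called in no region with all 6 libraries and no covariate. Zona glomerulosa was called as higher with depth class as a covariate in the gene body and TES (adjusted p = 0.0105 and 0.0194), without WT replicate 1 in the same regions (0.00533 and 0.00573) and without knockout replicate 3 at the TSS (0.0329). In the gene body cell cycle was called as lower without WT replicate 3 and knockout replicate 1 (adjusted p = 0.0294 and 0.026), fatty acid and lipid droplet as lower without WT replicate 2 (0.0134), Pol II subunits as higher without WT replicate 3 (0.0294) and p53 targets as higher without knockout replicate 3 (0.0364). Their gene body medians were 0.01 for cholesterol synthesis and uptake, 0.17 for zona glomerulosa, -0.09 for macrophage and myeloid, 0.07 for Pol II subunits, -0.00414 for RPB1 ubiquitylation and CUL3 adaptors and 0.02 for pausing and elongation factors. They were -0.18 for cell cycle, 0.11 for p53 targets, 0.04 for NRF2 targets, -0.08 for circadian clock, 0.06 for the cAMP and PKA pathway and -0.03 for fatty acid and lipid droplet, with adjusted p in the gene body from 0.0835 to 0.845. Single members of 4 of these lists rose. They were Fdps, an enzyme of isoprenoid synthesis (2.08-fold at the TES, adjusted p = 0.0235), Hexim1, an inhibitor of the elongation factor P-TEFb (1.99-fold at the TES, adjusted p = 0.0153), Gclc, an enzyme of glutathione synthesis (2.40-fold at the TES, adjusted p = 0.00106), and Abca1, a cholesterol exporter (1.81-fold at the TSS, adjusted p = 0.0454). The call of Abca1 ended with RLE scaling, table totals, limma-voom and joint table scaling (adjusted p = 0.0525, 0.1005, 0.0571 and 0.0934) and without WT replicate 1, WT replicate 2, WT replicate 3, knockout replicate 2 and knockout replicate 3 (0.2482, 0.2103, 0.058, 0.309 and 0.2953). That of Fdps ended with cyclic loess, joint table scaling and the enrichment covariate (adjusted p = 0.1081, 0.0825 and 0.0905) and without WT replicate 1, WT replicate 2, knockout replicate 1 and knockout replicate 2 (0.0648, 0.0503, 0.0522 and 0.2751). That of Hexim1 ended with joint table scaling (adjusted p = 0.0689) and without WT replicate 1 and knockout replicate 3 (0.1576 and 0.072), and that of Gclc with the enrichment covariate (0.0535). Rusc1 lies 224 bp from Fdps, so their windows may share counts. The X-zone, lymphocyte, adipocyte, Schwann and glia, and kidney tubule lists had 2, 2, 4, 4 and 1 genes in the tables and were not tested.

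Reference genes of the gland did not pass in any region in the edgeR test with all 6 libraries. Polr2a, which encodes RPB1, had 624 ± 61.1 CPM at the TSS in WT and 482 ± 21.6 in the knockout (log2 fold change -0.37 ± 0.17, adjusted p = 0.909), 473 ± 387 and 304 ± 104 in the gene body (adjusted p = 0.934) and 86.9 ± 17.1 and 108 ± 8.87 at the TES (adjusted p = 0.94). Its gene body values in WT were 277, 224 and 920 CPM. The gene body log2 fold change of Polr2a was -0.64, passed with the enrichment covariate (log2 fold change -1.26, adjusted p = 0.034) and turned to 0.28 without WT replicate 3 (adjusted p = 0.629). Chga at the TES passed without WT replicate 3 (log2 fold change 1.11, adjusted p = 0.0418). Star, which moves cholesterol into mitochondria, had gene body values of 595 ± 278 CPM in WT and 501 ± 52.0 in the knockout. Cyp11a1, which makes pregnenolone, had 319 ± 89.2 and 296 ± 26.8 CPM, Cyp11b1 310.3 ± 108 and 270.1 ± 5.87, Cyp21a1 87.1 ± 24.6 and 103 ± 20.2 and Hsd3b1 191 ± 78.5 and 202 ± 29.9. Mc2r, the receptor of adrenocorticotropic hormone, had 30.9 ± 4.85 and 36.7 ± 8.21 CPM, and Dbh, which makes noradrenaline, 48.0 ± 24.8 and 57.3 ± 23.5. The adjusted p of these genes in the gene body lay between 0.934 and 0.977. A 2-fold change was recovered in 60% of simulated gene body genes and a 1.5-fold change in 8%, so smaller changes of these genes were not detectable in most cases. These shares cover genes drawn at random. Genes that varied widely between WT mice, such as Star, Dbh and Polr2a, may be missed more often even at a 2-fold change.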

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

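The covariates for depth class and enrichment and the totals without Gm10800 were chosen after the data had been seen, and the other alternatives given here were planned. The counts of called genes moved most. Over the joint rows 39 calls became 62 with table totals only, 289 with DESeq2, 13 with the mouse number covariate, 370 with the enrichment covariate and 241 with the depth class covariate, and leaving out each library gave 0 to 78. At the TSS 43 calls became 95 with DESeq2, 75 with the mouse number covariate, 107 with joint table scaling, 98 with the enrichment covariate and 158 with the depth class covariate, and 5 to 84 without 1 library. In the gene body 32 calls became 179 with DESeq2, 0 with the mouse number covariate, 0 with joint table scaling, 193 with the enrichment covariate and 95 with the depth class covariate, and 0 to 37 without 1 library. At the TES 116 calls became 69 with cyclic loess, 61 with joint table scaling and 184 with the depth class covariate, and 73 to 148 without 1 library. For the TSS to gene body ratio 0 calls became 27 with the depth class covariate and were 0 to 0 without 1 library. For the TES to gene body ratio 2 calls became 0 with RLE scaling, 0 with gene body scaling, 0 with limma and 9 with the depth class covariate, and 0 to 15 without 1 library. Lists called with an estimated correlation or with fry were 0 at the TSS, 0 in the gene body and 0 at the TES, and the TSS count of 4 went from 1 to 6 without 1 library. The median of the oxidative phosphorylation list in the gene body turned to -0.004149 with the depth class covariate and to -0.022778 without WT replicate 2. Leaving out a library reduces the test to 2 against 3 mice. For the other settings the cause was not tested.

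The replicate number as a block was run as planned. With the replicate block 1 joint row, 100 TSS genes, 0 gene bodies, 194 TES genes, 0 TSS ratios and 0 TES ratios were called. The numbers do not pair the libraries, since the correlations of deviations between libraries with the same number were 0.44, -0.21 and 0.36 at the TSS, 0.08, -0.58 and 0.27 in the gene body and 0.03, -0.31 and 0.21 at the TES. Not every library correlated best with its own number, and WT replicate 2 did so with knockout replicate 1 in all 3 regions.

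All 43 TSS calls remained with DESeq2, the enrichment covariate and the depth class covariate, and all 32 gene body calls did so with the same 3 settings. Of the gene body calls 0 remained with joint table scaling or the mouse number covariate, and 0 without WT replicate 1 or any 1 knockout replicate. Of the TSS calls 39 remained with joint table scaling and 5 without knockout replicate 3. Of the 116 TES calls 88, 83 and 113 remained with these settings, 60 with cyclic loess and 61 with joint table scaling. Of the values of named genes under settings with all libraries, 1114 stayed on their side of the threshold, 82 lost it, 49 gained it and 0 reversed. Without 1 library the numbers were 563, 114, 13 and 0. Reversals were counted only where a value passed in at least 1 of the 2 settings, so changes of sign among values that did not pass, such as Polr2a in the gene body without WT replicate 3, are not among them. At these library depths, with the spread between mice and 3 mice per genotype, simulated 2-fold changes were recovered in 36% of TSS genes, 60% of gene body genes and 38% of TES genes, and depth was not varied on its own.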

Other observations

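The interferon-stimulated list, the tests of the one-sided calls and of Cwc22, and the splits of the libraries were chosen after the results had been seen.

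Genes induced by interferon were higher in the knockout in all 3 regions. A list of 53 such genes rose in 7 members at the TSS, 2 in the gene body and 20 at the TES, 0 fell, and 23 rose in at least 1 region. Its median log2 fold change was 0.61 at the TSS, 0.59 in the gene body and 0.88 at the TES, and 51, 53 and 52 of the 53 members were above 0 (camera with an estimated correlation, unadjusted p = 0.00727, 0.0103 and 0.0125; fry, unadjusted p = 0.00352, 0.00313 and 0.00706). The list was written from knowledge of the pathway after called genes had been seen, so these p-values are not independent evidence. At the TSS Oas1a, a sensor that makes 2'-5' oligoadenylate, went from 13.2 ± 4.74 to 52.7 ± 9.87 CPM (log2 fold change 2.07 ± 0.30, adjusted p = 0.0137), Isg15, a ubiquitin-like modifier, from 42.7 ± 2.61 to 121 ± 27.9 CPM (adjusted p = 0.00998), and Ifit3 from 21.0 ± 5.94 to 67.1 ± 3.96 CPM (adjusted p = 0.0137). Irf7, a transcription factor of the interferon response, went from 101 ± 11.3 to 205 ± 19.9 CPM at the TSS (adjusted p = 0.02). In the gene body Irf9, which is part of the factor that binds interferon response elements, went from 26.5 ± 1.63 to 51.5 ± 1.13 CPM (adjusted p = 0.0436) and Oasl2 from 24.4 ± 3.45 to 54.8 ± 2.39 CPM (adjusted p = 0.0368). The gene body calls of Irf9 and Oasl2 ended with joint table scaling and the mouse number covariate, where 0 gene bodies were called. They also ended without WT replicate 1 and without each knockout replicate. At the TES Ifit3b, Ifit1 and Rsad2 rose by 1.82, 1.53 and 1.08 on the log2 scale (adjusted p = 9.33e-05, 0.000109 and 0.00524). Members of the Ifit and Oas families have similar copies that can share reads.

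For the interferon genes 3 other explanations were set against a genotype-related interferon response. More macrophages in knockout glands would itself be a difference between the genotypes. If the pattern came only from picking called genes, the 30 members called in no region should lie near 0, but their gene body median was 0.463, against 0.0723 at the 95th percentile of 10000 random lists matched on counts. The shift was thus not confined to called genes. Interferon genes move together (estimated correlation 0.22 in the gene body) and random lists do not. This percentile therefore cannot tell genotype from a difference between individual mice. If knockout glands held more macrophages, the macrophage and myeloid list should move at least as far, but its gene body median was -0.0942, and 0 interferon genes were on the macrophage or lymphocyte lists. If unequal ChIP enrichment were the cause, the gene body median should shrink with depth class as a covariate. In fits to log2 CPM it was 0.579 without the covariate and 0.653 with it. Depth class was set by total counts, but it also separated the libraries by the TSS to gene body ratio without Gm10800. In the 3 libraries with the most counts this ratio was 0.136 in WT and 0.148 and 0.125 in the knockout. Among the 3 libraries with the fewest counts, it was 0.0897 and 0.0702 in WT and 0.108 in the knockout. An enrichment difference along genotype can thus remain, so this test does not exclude unequal enrichment. A genotype-related interferon response therefore stays a hypothesis, and a difference in infection, housing or litter between the 3 and 3 mice and a change in other immune cells were not tested.

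Of called genes 100% of 43 at the TSS and 89.7% of 116 at the TES were higher in the knockout. At the TSS unequal enrichment between libraries would leave fewer or more even calls once depth class is a covariate, but 90.5% of 158 TSS calls were then higher. Depth class was set by total counts, and it also separated the libraries by their TSS to gene body ratio. With the enrichment covariate 93 of 98 TSS calls were higher. Scaling stays open, since at least 98.3% of TSS calls were higher with table totals, RLE and cyclic loess, but these lowered the median log2 fold change of all genes by at most 0.00189, against 0.86 for the smallest called change, and so could not have evened the directions. At the TES the share was 84.8% with depth class as a covariate and 80.3% of 61 with joint table scaling. It was 78.7% without WT replicate 1 and without knockout replicate 1, so the excess at the TES stays open. In the gene body 31 of 32 calls were higher, 94 of 95 with depth class as a covariate and 185 of 193 with the enrichment covariate. The excess there thus remained with these covariates, but 0 gene bodies were called with joint table scaling. Of 27 TSS ratios called with depth class as a covariate 9 were higher, but a ratio does not give the direction within a region. A genotype effect on polymerase occupancy and differences between individual mice stay open as well.

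Cwc22 at the TES gave the largest fall among called genes. Its gene body counts were 451, 94.0 and 1313 CPM in the WT libraries, a 14.0-fold range, and 97.7, 91.8 and 112 CPM in the knockout libraries. At the TES they were 79.2, 28.4 and 193 CPM in WT and 10.7, 5.48 and 1.97 CPM in the knockout. A copy number or strain difference between mice of this mixed background may underlie the spread in WT, and genotype and such a difference cannot be told apart here, since the ranks of the libraries matched only in part between regions (smallest Spearman correlation 0.6) and DNA copy number was not analysed here.

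Each count of calls was set against the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. The joint table gave 39 calls for genotype and at most 4215 for another split, and 2 splits gave at least as many calls as the real one. Each such number of splits includes the real split itself. The TSS gave 43 and 1653 (2 splits), the gene body 32 and 1 (1 split), the TES 116 and 12 (1 split), the TSS ratio 0 and 3205 (10 splits) and the TES ratio 2 and 89 (2 splits). The highest other value in each case came from the split of WT replicates 1 and 2 and knockout replicate 1 from the other 3 libraries. That split follows the total counts, the Gm10800 share and the TSS to gene body ratio. It points to a structure of the samples other than genotype. With depth class as a covariate genotype gave 241 joint rows, 158 TSS genes, 95 gene bodies, 184 TES genes, 27 TSS ratios and 9 TES ratios.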
